A study of Mus musculus with 19 samples.

How the data were processed

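RNA was sequenced from hippocampal microglia of mice, sorted by flow cytometry for CD11b and CD45, in 15 libraries made with a low-input full-length cDNA kit and a tagmentation kit, per the labels' protocols. The kits named in the labels do not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. The libraries fall into 5 groups of 3. At 3 months, mice with an inducible Cre recombinase in microglia, with or without floxed PU.1 alleles, received tamoxifen at 50 mg/kg on 5 days, and tissue was taken 1 week later. At 4.5 months, the groups were CK control, CK-p25 and CK-p25 with the PU.1 conditional knockout (cKO), all carrying the inducible Cre, treated with the same tamoxifen course at p25 induction and collected 6 weeks later. A further 4 samples of chromatin immunoprecipitation (PU.1 and input, CK and CK-p25) are described in the labels and are not analysed here.

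The authors deposited 2 tables of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of a library), one for the 3-month and one for the 4.5-month libraries, each with 23951 genes. TopHat, Bowtie, Cufflinks 2.0.0 and the mm9 genome build are named in the submitters' processing notes. The 15 columns were matched to samples by the exact description in the labels. For the 3-month table the labels contradict each other: the description ties the columns named for PU.1 to the samples titled as controls, while the source name points the other way. The titles and descriptions were followed, the libraries are called "labelled PU.1 cKO" and "labelled control", and the other reading would turn the sign of each 3-month difference. No genome of the build was used here, so no coordinates are given. Of the gene symbols, 23836 matched a current or older symbol in a gene table of the GRCm38.p6 assembly.

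The unit is not a count, so no count model was fitted, and the number of reads per library is unknown. Summed FPKM per library ran from 449784 to 622613 at 3 months and from 475007 to 650063 at 4.5 months, which is not a depth. The value of a single read relative to the first library of the table was estimated from low small-RNA genes. It lay between 0.763 and 1.01 at 3 months and between 0.893 and 1.51 at 4.5 months. The highest value, 1.51, belonged to CK-p25 replicate 3 and rested on 2 genes. Some abundant genes are listed at exactly 0 in some libraries and high in others. Where that occurred, library values are given in place of a fold. Leaving out the genes listed at 0 in 1 library and at 100 FPKM or more in another was an alternative chosen after seeing the data.

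Values were analysed as log2(FPKM + 1) with a pseudocount of 1, over genes with a mean of at least 1 FPKM across the libraries of the table: 10845 genes at 3 months and 10894 at 4.5 months. A fold on this scale understates the change of genes with low values. Groups were compared with limma 3.58.1 in R 4.3.3 (moderated linear models with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. The 6 libraries of the 3-month table were fitted together. The 9 libraries of the 4.5-month table were fitted in 1 model with a shared estimate of the spread. Differences are given as log2 values with the standard error (SE) of the model, and levels as mean ± SD over 3 libraries. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

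In total 24 gene lists were fixed before the data were examined. They cover homeostatic and disease-associated microglia, interferon response, antigen presentation, inflammatory cytokines and NF-kB, complement, phagocytosis and Fc receptors, textbook PU.1 targets, myeloid transcription factors, mouse orthologs of Alzheimer's risk genes, cell cycle, cholesterol synthesis and uptake, cholesterol efflux, glycolysis, markers of neurons, astrocytes, oligodendrocytes, endothelium, border macrophages, monocytes, neutrophils and lymphocytes, and dissociation stress. The last list, of sex-linked genes, checked the libraries and was not tested. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and the rotation test fry as alternatives. The disease-associated, risk, phagocytosis and PU.1 target lists share members. The homeostatic list shares Sall1 with the myeloid transcription factors and Csf1r with the PU.1 targets. Cholesterol efflux and risk lists share Apoe. Results of lists that share members are not independent.

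Named genes followed a rule fixed before the data were examined. Spi1, which encodes PU.1, comes first. Then come the 8 largest rises and the 8 largest falls per comparison among genes past the threshold whose libraries do not overlap between groups. Where fewer than 3 passed in a direction, the 3 with the smallest p are given and said not to have passed. Of each list the text describes, up to 4 members with the smallest p are named. Unnamed gene models, small RNAs and rows with several symbols were counted but not named. Single-gene results withheld for evaluation are not reported. The script was tested on simulated data made from the real libraries' means and spread, with 200 changed genes in each of 20 sets. Each set mixed changes of 0.5, 1, 2 and 3 on the log2 scale. The shares recovered depend on that mix and on the number of changed genes, which differ from the real data. Of genes changed by 1 on the log2 scale, 24.4% were recovered in the 3-month comparison among 10845 genes. In the 4.5-month comparisons, among 10894 genes, recovery was 68.1% for CK-p25 against CK, 66.1% for CK-p25 PU.1 cKO against CK-p25 and 68.1% for CK-p25 PU.1 cKO against CK.

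Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median centring, quantile normalization, no variance trend, a replicate block, leaving out small RNAs and gene models, only the libraries compared, and leaving out each library in turn. The last was not planned for the correlation between the 3-month difference and that of CK-p25 PU.1 cKO from CK-p25. The labels carry run tags: 180202 for the 3-month libraries, 180620 for CK-p25 replicate 3 and 160706 for the remaining 8. The tag of CK-p25 replicate 3 occurs in a single library, so the fit without that library gives the within-batch values.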

Results

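Hippocampal microglia were profiled by RNA sequencing in 5 groups of 3 libraries. The 3-month set compared tamoxifen-treated mice that carry an inducible Cre in microglia, with and without floxed alleles of Spi1, the gene of the myeloid transcription factor PU.1. The 4.5-month set compared 3 groups: CK control mice, CK-p25 mice, in which forebrain neurons can be induced to express the Cdk5 activator p25 and then degenerate, and CK-p25 mice with the PU.1 conditional knockout (cKO). Values are FPKM, and the read depth of the libraries is unknown. Between 10253 and 10738 genes reached 1 FPKM in a 3-month library and between 10140 and 10954 in a 4.5-month library. CK-p25 replicate 3, the only library of its run, stood apart from the other 4.5-month libraries. In it 42.1% of genes were listed at 0, and it held 19.1% of the variation within groups in that set.

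Spi1, the targeted gene, went against the sample titles in the 3-month set, but it was lower in the columns named for PU.1. It measured 409, 338 and 337 FPKM in the libraries labelled PU.1 cKO (mean 362 ± 41.4, SD, n = 3) and 261, 105 and 248 FPKM in those labelled control (205 ± 86.3). The log2 difference of 0.92 ± 0.35 (SE) did not pass the threshold (adjusted p = 0.0853), though the 2 groups did not overlap. The same lack of overlap held for 48.8% of the 10845 genes tested in this comparison. The Spi1 difference passed after quantile normalization (1.14, adjusted p = 0.0126) and without labelled control replicate 2 (0.50, adjusted p = 0.0478). At 4.5 months Spi1 measured 257, 230 and 251 FPKM in CK, 251, 208 and 298 in CK-p25, and 165, 152 and 224 in CK-p25 PU.1 cKO. The mean in CK-p25 PU.1 cKO, 180 ± 38.5 FPKM, lay below the 252 ± 45.1 of CK-p25 by -0.49 ± 0.17 on the log2 scale (95% interval -0.88 to -0.09), with an adjusted p of 0.745. Against CK, at 246 ± 14.1 FPKM, the difference was -0.46 ± 0.17 (adjusted p = 0.0751). It passed without CK-p25 replicate 3, which enters the shared spread (adjusted p = 0.0407), without CK-p25 PU.1 cKO replicate 3 (-0.63, adjusted p = 0.0221), after quantile normalization (-0.85, adjusted p = 0.00495) and with only the compared libraries (adjusted p = 0.0464). CK-p25 and CK differed by 0.02 ± 0.17 (adjusted p = 0.933). A gene-level FPKM also counts parts of the transcript that a Cre deletion leaves in place, so it need not fall with the protein.

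**Figure D1:**
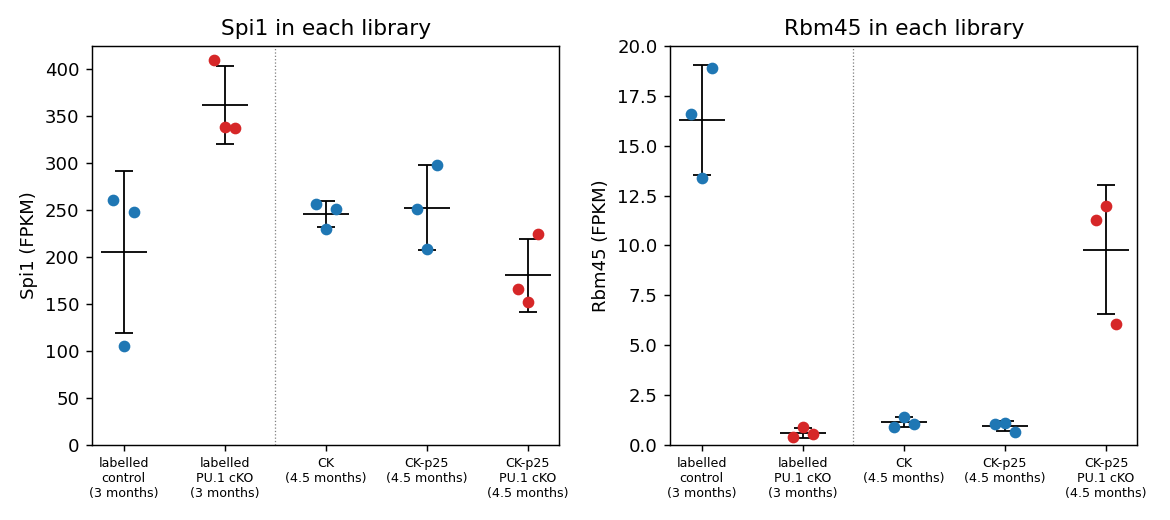
FPKM of Spi1 (left) and of Rbm45 (right) in each of the 15 libraries, with the mean and SD of each group (n = 3). Red points are libraries labelled PU.1 cKO and blue points the others. Spi1 averaged 362 FPKM in the 3-month libraries labelled PU.1 cKO and 205 in those labelled control, but 180 in CK-p25 PU.1 cKO against 252 in CK-p25.

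CK-p25 was set against CK to ask how microglia differ in the degenerating hippocampus. Spp1 (osteopontin) averaged 1959 ± 333 FPKM in CK-p25 microglia against 9.23 ± 4.87 in CK, a log2 difference of 7.68 ± 0.37. Cst7, which encodes cystatin F, averaged 1560 ± 189 against 15.4 ± 1.41 FPKM, and the transmembrane glycoprotein gene Gpnmb 95.2 ± 28.3 against 0.384 ± 0.183 FPKM. Among other large rises were the chemokine genes Ccl5 (log2 5.38 ± 0.37) and Cxcl13 (5.74 ± 0.67), the fatty acid binding protein gene Fabp5 (5.33 ± 0.27) and Cox6a2 (5.51 ± 0.29). Cxcl13 was uneven in CK-p25, at 111 ± 105 FPKM. H2-Q7 rose by 5.79 ± 0.37, but this class I gene has near-identical copies, so its own level is uncertain. The largest falls were in Gpr165 (83.7 ± 6.06 FPKM in CK, 1.61 ± 0.299 in CK-p25), Gp9 (log2 -4.19 ± 0.26), Tmem204 (-4.04 ± 0.31), Bank1 (-3.31 ± 0.26), Upk1b (-3.14 ± 0.56), Nrarp (-2.87 ± 0.21) and Slco4a1 (-2.82 ± 0.25). Amd1 also passed (-3.16 ± 1.02, adjusted p = 0.0458), but it measured 19.99, 0.0376 and 0.0342 FPKM in CK-p25 against 23.4 to 25.8 in CK. It was at -4.61 without CK-p25 replicate 1 and, not past the threshold, at -2.44 and -2.43 without replicates 2 and 3. The call was also lost without any 1 of CK replicates 1, 2 or 3, with no filter (adjusted p = 0.0808), without the variance trend (0.0503) and with only the compared libraries (0.103).

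Markers of disease-associated microglia were higher as a group in CK-p25. Of 22 tested members 21 rose, with a list median of 3.95. Examples are Clec7a (4.54 ± 0.12), the growth factor gene Csf1 (4.20 ± 0.09) and Lgals3 (3.70 ± 0.14). Adjusted over the list alone, 21 were higher and 1 was lower. The exception is Ctsd (cathepsin D), listed at 0 in CK-p25 replicates 1 and 2 beside 30706 FPKM in replicate 3 and 12960 to 14566 FPKM in CK. Interferon response genes rose in 20 of 21 cases (21 adjusted over the list alone; median 3.60), among them Ifi27l2a (4.33 ± 0.19), Oasl2 (4.27 ± 0.24), Ifit2 (3.77 ± 0.19) and Oas1a (3.60 ± 0.15). Antigen presentation genes rose in 10 of 14 cases (12 adjusted over the list alone; median 1.82), including H2-D1 (3.55 ± 0.25), H2-K1 (3.26 ± 0.12) and the class I transactivator gene Nlrc5 (1.95 ± 0.15). CK replicate 1 was low in class II genes, with H2-Aa at 2.29 FPKM against 166.2 and 100.7 in the other CK libraries, and in the border macrophage marker Mrc1 (0.902 against 41.9 and 43.3 FPKM). The camera test gave adjusted p = 2.27e-18, 5.67e-17 and 2.68e-07 for the 3 lists, and adjusted p = 0.0543, 0.192 and 0.214 with an estimated correlation.

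Complement genes rose in 9 of 12 cases (9 higher and 1 lower adjusted over the list alone), among them Cfb at 4.88 ± 0.82, C3 at 4.63 ± 0.42, C1qb at 1.13 ± 0.16 and C3ar1 at 0.80 ± 0.07 (camera adjusted p = 0.000676; adjusted p = 0.141 with an estimated correlation). Of 16 cytokine and NF-kB genes 10 rose, among them Ccl3 (2.63 ± 0.19) and Ccl4 (2.59 ± 0.27), and Il6 fell by 1.58 on the log2 scale (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000851; adjusted p = 0.48 with an estimated correlation). Glycolysis genes rose in 11 of 14 cases and 1 fell, with Pkm at 1.76 ± 0.10 and Tpi1 at 1.63 ± 0.15 (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.83e-06; adjusted p = 0.265 with an estimated correlation). Textbook PU.1 targets rose in 11 of 19 cases and fell in 2, with Cybb at 3.45 ± 0.48, Csf2ra at 2.07 ± 0.08 and Tlr4 at -0.82 ± 0.07 (13 higher and 4 lower adjusted over the list alone). Their list had a camera adjusted p of 0.0167, an adjusted p of 0.265 with an estimated correlation, and 0.192 after quantile normalization.

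Homeostatic microglia genes fell in 14 of 18 cases (15 adjusted over the list alone; median -0.77), among them the purinergic receptor genes P2ry12 (-2.12 ± 0.14) and P2ry13 (-1.57 ± 0.13), Slc2a5 (-2.08 ± 0.25) and Tmem119 (-1.58 ± 0.14). For this list the camera adjusted p was 1.22e-08 (adjusted p = 0.192 with an estimated correlation). Of 18 myeloid transcription factor genes 9 fell, including Maf (-1.34 ± 0.12) and Sall1 (-1.13 ± 0.11), and 1 rose, Bhlhe40 (4.40 ± 0.19). Adjusted over the list alone, 3 were higher and 10 lower. The camera adjusted p was 0.0334, the adjusted p with an estimated correlation 0.192, and the adjusted p without CK-p25 replicate 3 was 0.0571. The lists that did not pass were phagocytosis and Fc receptors (adjusted p = 0.0504), cell cycle (0.0504), cholesterol efflux (0.0606), dissociation stress (0.0763), cholesterol synthesis (0.166) and risk orthologs (0.349). The same holds for markers of astrocytes (0.166), oligodendrocytes (0.484), monocytes (0.486), endothelium (0.706), neurons (0.85), neutrophils (0.85), lymphocytes (0.85) and border macrophages (0.888). Single markers of other cells did pass beside these groups: astrocytic Gfap (4.02 ± 0.85; 27.6, 203 and 32.0 FPKM in CK-p25 against at most 4.13 in CK), oligodendrocytic Cnp (0.39 ± 0.13), endothelial Flt1 (2.17 ± 0.16) and Pecam1 (-2.29 ± 0.36), and Fn1 of the monocyte list (2.17 ± 0.61). Of the dissociation stress list Atf3 (2.34 ± 0.23) and Ier3 (0.78 ± 0.20) passed. Neutrophil S100a8 reached 459 FPKM in CK-p25 replicate 2 and was listed at 0 in replicate 1.

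In all, 3412 of 10894 genes differed between CK-p25 and CK, 1922 higher and 1490 lower, of which 666 and 281 by over 2-fold. The split of calls depends on scaling: 56.3% were higher as deposited, 53.6% after median centring and 45.6% after quantile normalization. Within the run that holds 8 of the 9 libraries, without CK-p25 replicate 3, the counts were 2360 higher and 2162 lower. Without CK replicate 1, 2 or 3 the lower genes numbered 908, 902 and 941.

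CK-p25 PU.1 cKO microglia were set against the same CK libraries. Gpnmb averaged 304 ± 170 FPKM (log2 7.57 ± 0.47), Spp1 1743 ± 536 (7.48 ± 0.37) and Cst7 1332 ± 463 (6.28 ± 0.25). Also higher were Ccl5 (5.91 ± 0.37), the complement gene C3 (5.86 ± 0.42), Cxcl13 (5.67 ± 0.67) and Fabp5 (5.54 ± 0.27). Apoc4 measured 187, 142 and 21.3 FPKM and was listed at 0 in CK replicates 2 and 3. It adjoins Apoc2, so its level is uncertain. Lower were Gpr165 (-5.16 ± 0.31), Upk1b (-4.39 ± 0.56), Tmem204 (-4.30 ± 0.31), Ecscr (-4.22 ± 0.40), Gp9 (-4.20 ± 0.26), the interleukin 7 receptor gene Il7r (-3.48 ± 0.30) and Slco4a1 (-3.37 ± 0.25). Ctsd was listed at 0 in all 3 CK-p25 PU.1 cKO libraries, and no fold is given.

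Of the disease-associated list 21 of 22 members rose and 1, Ctsd, was called lower from its zeros (median 4.05; the same counts adjusted over the list alone). The Ctsd call was lost without CK-p25 PU.1 cKO replicate 1 (adjusted p = 0.0526) or 2 (0.053) and without CK replicate 1 (0.0528), 2 (0.0525) or 3 (0.0518). Interferon genes rose in 20 of 21 cases (21 adjusted over the list alone; median 3.64) and antigen presentation genes in 9 of 14 (10 adjusted over the list alone). Complement genes rose in 9 of 12 cases (9 higher and 1 lower adjusted over the list alone) and glycolysis genes in 12 of 14 (12 adjusted over the list alone). Among cytokine genes 7 of 16 rose and 2 fell (11 and 3 adjusted over the list alone), with Il6 at -2.49 ± 0.21. Homeostatic genes fell in 16 of 18 cases (17 adjusted over the list alone), with P2ry12 at -2.26 ± 0.14. Of 21 cell cycle genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with Ube2c at -1.25 ± 0.23 and Pcna at 0.55 ± 0.11. In that order, camera gave adjusted p = 5.5e-18, 1.05e-16, 6.58e-06, 0.00106, 7.71e-07, 0.0171, 2.57e-10 and 0.0348. With an estimated correlation the adjusted p was 0.0573, 0.246, 0.252, 0.161, 0.252, 0.612, 0.186 and 0.628. The cell cycle call was also lost with a filter at 5 FPKM (adjusted p = 0.94), after quantile normalization (0.0867), with only the compared libraries (0.0534), without CK-p25 PU.1 cKO replicate 3 (0.113) and without CK replicate 1 (0.132). The cytokine call was lost without CK replicate 1 (0.0501).

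The lists that did not pass were myeloid transcription factors (adjusted p = 0.0703), phagocytosis (0.0746), cholesterol efflux (0.0746), PU.1 targets (0.0762), cholesterol synthesis (0.0762), dissociation stress (0.211) and risk orthologs (0.402). For markers of other cells the adjusted p was 0.129 for astrocytes, 0.169 for monocytes, 0.402 for oligodendrocytes, 0.532 for endothelium, 0.539 for border macrophages and for lymphocytes, 0.64 for neurons and 0.908 for neutrophils. Single markers passed in 5 of these lists: Gfap (4.17 ± 0.85) and Aldh1l1 (1.31 ± 0.35) of astrocytes, Cspg4 (3.80 ± 0.93) of the oligodendrocyte list, endothelial Flt1 (2.42 ± 0.16) and Pecam1 (-2.75 ± 0.36), Fn1 (3.63 ± 0.61) of monocytes and Cd79b (-1.95 ± 0.56) of lymphocytes. Of the dissociation stress list 2 of 12 members were higher (1 adjusted over the list alone). Altogether 1937 genes were higher and 1447 lower than in CK. Higher calls made up 57.2% as deposited and 45.9% after quantile normalization. Without CK-p25 replicate 3, which is in neither group but enters the shared spread, the counts were 2650 and 2398. The lower genes numbered 908 without CK-p25 PU.1 cKO replicate 2, and 946, 953 and 951 without CK replicates 1, 2 and 3.

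**Figure D2:**
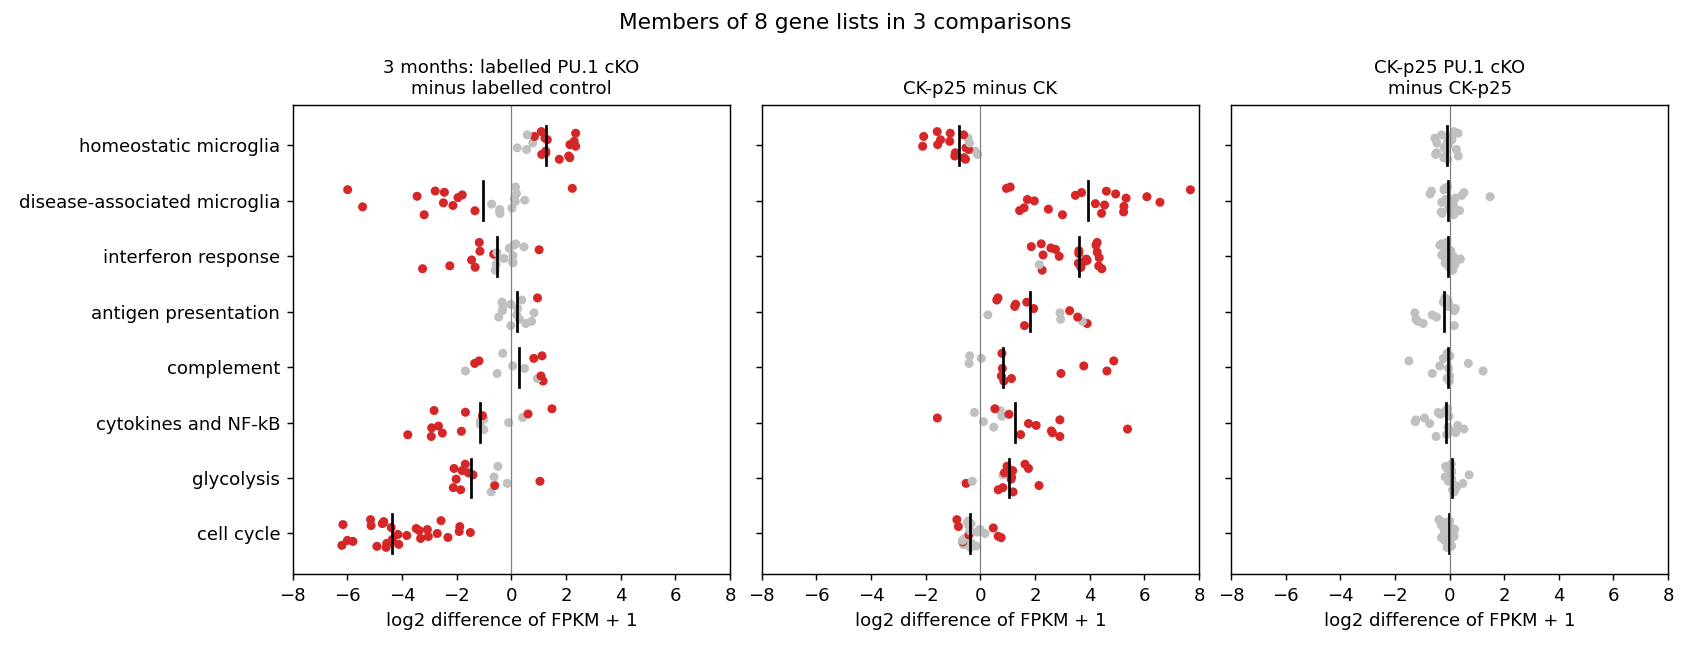
Each point is a member of 1 of 8 gene lists, placed at its log2 difference of FPKM + 1 in 3 comparisons. Red points passed the threshold in limma, grey points did not, and black bars are list medians. Ctsd, listed at 0 in 5 of the 4.5-month libraries, is left out of the points in the panels of that age. Disease-associated genes have a median of 3.95 in CK-p25 against CK and of -0.06 in CK-p25 PU.1 cKO against CK-p25. In the 3-month set, as labelled, the cell cycle median is -4.35.

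CK-p25 PU.1 cKO was set against CK-p25 to ask what loss of PU.1 changes in microglia of the degenerating hippocampus. No gene passed the threshold in either direction with limma. At an unadjusted p under 0.05 there were 671 genes, where 545 are expected by chance, and 9.38% of genes had non-overlapping groups against 10% by chance. The genes with the smallest p did not pass. Rbm45, an RNA-binding protein gene, measured 11.3, 12 and 6.06 FPKM in CK-p25 PU.1 cKO against 1.06, 1.11 and 0.634 in CK-p25 (log2 2.44 ± 0.24, adjusted p = 0.0765). It did pass after quantile normalization (adjusted p = 0.0418), without small RNAs and gene models (0.0322) and without CK-p25 PU.1 cKO replicate 3 (0.00542). The lymphotoxin gene Ltb differed by 1.56 ± 0.30, Mlph by -1.17 ± 0.20, Tmem163 by -1.13 ± 0.19 and the scavenger receptor gene Scarb1 by -0.78 ± 0.14, each with an adjusted p of 0.745. Hba-a2, a hemoglobin gene, measured 2.92, 4.43 and 17.0 FPKM and was listed at 0 in each CK-p25 library.

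None of the 23 lists passed in this comparison, and in each the count of members past the threshold was 0. Homeostatic genes had a median of -0.09 (Fcrls at -0.51 ± 0.10, Siglech at -0.54 ± 0.16; 1 lower adjusted over the list alone) and cytokine genes of -0.13 (Il6 at -0.92 ± 0.21, Il1b at -1.23 ± 0.53; 1 lower adjusted over the list alone), both with a camera adjusted p of 0.212. PU.1 targets had a median of -0.07 (adjusted p = 0.221), interferon genes of -0.05 (0.644) and disease-associated genes of -0.06 (0.862), with Gpnmb at 1.48 ± 0.47 and Lgals3 at 0.53 ± 0.14. Glycolysis genes (0.232) had 1 higher adjusted over the list alone. The remaining lists had adjusted p values of 0.267 (antigen presentation), 0.68 (complement), 0.501 (phagocytosis), 0.595 (myeloid transcription factors), 0.827 (risk orthologs), 0.565 (cell cycle), 0.52 (cholesterol synthesis), 0.406 (cholesterol efflux) and 0.294 (dissociation stress). For markers of other cells they were 0.232 for border macrophages, for monocytes and for lymphocytes, 0.272 for neurons, 0.73 for astrocytes, 0.795 for oligodendrocytes and for neutrophils, and 0.68 for endothelium. Without CK-p25 PU.1 cKO replicate 3, 12 genes were higher and 13 lower, Gpnmb among the higher and Scarb1 among the lower (adjusted p = 0.0251 each). Without CK-p25 PU.1 cKO replicate 1, 8 lists passed and without CK-p25 replicate 2, 7 did. In both of these fits neuron, astrocyte and monocyte markers were higher and the homeostatic and cytokine lists lower (adjusted p = 0.0479 and 0.0243 for either of the last 2). Without CK-p25 PU.1 cKO replicate 1, markers of lymphocytes (adjusted p = 1.31e-05) and border macrophages (0.0176) were higher too and PU.1 targets lower (0.0479). Without CK-p25 replicate 2, neutrophil markers were higher (0.0114) and antigen presentation genes lower (0.0367). Glycolysis genes were higher without CK-p25 PU.1 cKO replicate 3 (0.0352) and border macrophage markers without CK replicate 1 (0.00956). Without CK-p25 replicate 3, that is within 1 run, 2 lists passed: interferon response, higher, and cholesterol efflux, lower (adjusted p = 0.0482 each).

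The same data give how far CK-p25 PU.1 cKO microglia stood from CK for the genes that separate CK-p25 from CK. Over the 1922 genes higher in CK-p25, the median log2 difference from CK was 0.78 in CK-p25 and 0.74 in CK-p25 PU.1 cKO. Over the 1490 lower genes it was -0.62 and -0.55. The median step toward CK over all 3412 genes was 0.042, with 0.006, 0.063 and 0.058 in the 3 CK-p25 PU.1 cKO libraries. It was 0.107 without CK-p25 replicate 2, 0.087 without CK-p25 replicate 1, and 0.026 without CK-p25 replicate 3 or without CK-p25 PU.1 cKO replicate 2. Genes picked in CK-p25 step back by chance, and 20 simulated sets with no effect of the knockout gave a median of 0.024, from 0.019 to 0.030. The step varied more between the real CK-p25 PU.1 cKO libraries (SD 0.032), so this range does not decide whether the step exceeds chance. The simulated sets were not matched to the fits with a library left out. None of the 3412 genes was called with the opposite sign in CK-p25 PU.1 cKO against CK-p25. Opposite calls numbered 2 and 6 without CK-p25 PU.1 cKO replicates 2 and 3, 1 and 1 without CK replicates 1 and 2, and 4 and 2 without CK-p25 replicates 1 and 2. Apart from the fit without CK-p25 PU.1 cKO replicate 3, the genes called in these fits were small RNAs. The exceptions were Amd1 and Supt16, both without CK-p25 replicate 1.

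Across genes, the differences of both CK-p25 groups from CK had a Pearson r of 0.851 and a Spearman rho of 0.865, and 1613 genes were higher and 1078 lower in both, with 0 in opposite directions. Genes are not independent replicates. Independent lists of these sizes would share 342 and 198 genes. The groups share their CK libraries, which alone gave r = 0.512 in simulation. The covariance was 0.570 against 0.092 simulated, a difference of 0.478. Part of the overlap may come from the shared controls, which are too few to split.

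**Figure D3:**
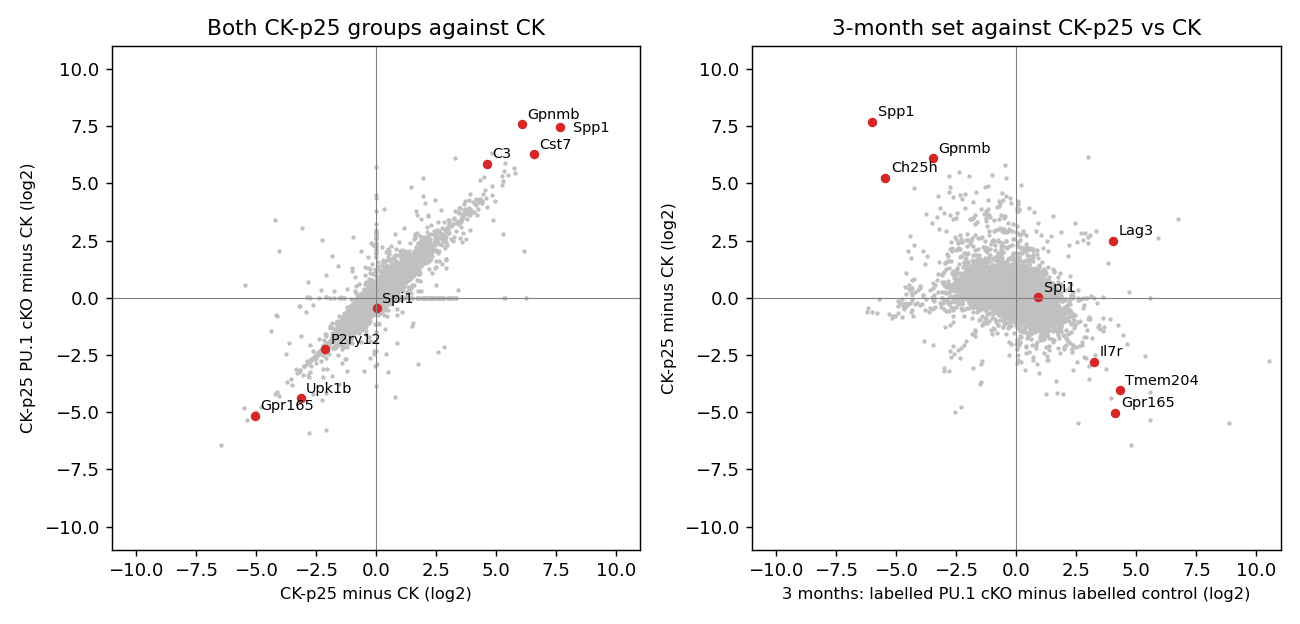
Each grey point is a gene at its log2 differences of FPKM + 1, with Ctsd left out and named genes in red. Left, CK-p25 against CK (horizontal) and CK-p25 PU.1 cKO against CK (vertical), r = 0.851 across genes with shared CK libraries. Right, the 3-month difference as labelled (horizontal) and CK-p25 against CK (vertical), r = -0.393 with no shared library.

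The 3-month set was made to compare microglia with and without PU.1 shortly after deletion. Directions here follow the sample titles and descriptions, which Spi1 contradicts. Cell division genes were far lower in the libraries labelled PU.1 cKO: Birc5 (survivin) averaged 1.21 ± 0.504 FPKM against 168 ± 63.0 in those labelled control, the ribonucleotide reductase gene Rrm2 1.18 ± 0.156 against 171 ± 81.7, and the cyclin gene Ccnb2 0.927 ± 0.442 against 125 ± 40.1. Ccnb1 (-5.80 ± 0.41), Ube2c (-5.16 ± 0.27) and Plk1 (-5.13 ± 0.28) were lower too. So were Spp1 (7.60 ± 6.00 against 462 ± 31.3 FPKM) and Ch25h, which encodes cholesterol 25-hydroxylase (log2 -5.45 ± 0.44). Higher in the libraries labelled PU.1 cKO were Gpr56 (536 ± 57.6 against 41.7 ± 9.66 FPKM), Tmem204 (63.0 ± 6.55 against 2.39 ± 1.36), Gpr165 (log2 4.13 ± 0.29), the immune receptor gene Lag3 (4.02 ± 0.17), Chst8 (3.45 ± 0.28), Atp8a2 (3.35 ± 0.30), Mycl (3.27 ± 0.28) and Il7r (3.25 ± 0.24).

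In the libraries labelled PU.1 cKO all 29 tested cell cycle genes were lower (29 adjusted over the list alone), with a median of -4.35 and Top2a at -4.68 ± 0.17, Tpx2 at -4.67 ± 0.21 and Bub1b at -4.56 ± 0.19. Homeostatic genes were higher in 14 of 18 cases (17 adjusted over the list alone; median 1.26), with Tgfbr1 at 2.35 ± 0.31, P2ry12 at 2.35 ± 0.24 and Cst3 at 2.14 ± 0.28. Disease-associated genes were lower in 11 of 22 cases and higher in 1 (12 and 1 adjusted over the list alone; median -1.03), with Ank at -3.19 ± 0.20 and Cst7 at -2.49 ± 0.22. Cytokine genes were lower in 9 of 17 cases and higher in 2 (11 and 2 adjusted over the list alone; median -1.14), with Ccl2 at -3.79 ± 0.27 and Tnf at -2.83 ± 0.21. The camera adjusted p was 5.37e-23, 2.57e-08, 0.00126 and 0.00376 for these lists. With an estimated correlation the adjusted p was 0.262, 0.262, 0.35 and 0.35.

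Of the metabolic lists, cholesterol synthesis and glycolysis were also lower as labelled, and cholesterol efflux was not. Cholesterol synthesis and uptake genes were lower in 11 of 14 cases (13 adjusted over the list alone; median -1.39), with the squalene epoxidase gene Sqle at -4.32 ± 0.46 and the isopentenyl diphosphate isomerase gene Idi1 at -2.49 ± 0.35. Glycolysis genes were lower in 9 of 14 cases and higher in 1 (11 and 1 adjusted over the list alone; median -1.49), with Gapdh at -2.13 ± 0.23 and Pkm at -2.10 ± 0.32. Their camera adjusted p was 2.7e-05 and 0.000612, and the adjusted p was 0.463 and 0.35 with an estimated correlation. Risk orthologs were higher in 6 of 18 cases (9 adjusted over the list alone), with Trem2 at 2.23 ± 0.33 and Cd33 at 1.49 ± 0.24. Myeloid transcription factors were higher in 9 of 18 cases and lower in 2 (10 and 4 adjusted over the list alone), with Fli1 at 1.16 ± 0.18 and Bhlhe40 at -2.62 ± 0.35. PU.1 targets were higher in 6 of 19 cases and lower in 1 (8 and 1 adjusted over the list alone), with Csf1r at 1.75 ± 0.25 and Csf3r at 1.55 ± 0.20. Camera gave adjusted p = 0.00211, 0.0167 and 0.0417, and adjusted p = 0.262, 0.35 and 0.606 with an estimated correlation. The PU.1 target list did not pass after quantile normalization (0.0594), without labelled cKO replicate 3 (0.052) or without labelled control replicate 2 (0.247).

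Border macrophage and monocyte markers moved with these groups and were lower in the libraries labelled PU.1 cKO, though neither list passed with an estimated correlation. Border macrophage genes were lower in 4 of 8 cases (5 adjusted over the list alone; camera adjusted p = 0.0417), with Lyve1 at 10.7, 9.60 and 12.8 FPKM against 35.6, 157 and 31.7. That list did not pass with a filter at 5 FPKM (0.0547), after quantile normalization (0.108), or without labelled cKO replicate 1 (0.0861) or labelled control replicate 2 (0.168). Monocyte genes were lower in 2 of 7 cases (3 adjusted over the list alone; camera adjusted p = 0.0167; 0.0547 with a filter at 5 FPKM), with S100a4 at -4.59 ± 0.58. With an estimated correlation the adjusted p was 0.638 and 0.35. Neutrophil S100a8 measured 4831 FPKM in labelled control replicate 1 and at most 99.0 in the other 5 libraries. Lists that did not pass were interferon response (7 of 20 lower and 1 higher, adjusted p = 0.0942), phagocytosis (0.122), cholesterol efflux (0.134), complement (0.445), dissociation stress (0.445) and antigen presentation (0.478). The same holds for markers of oligodendrocytes (0.312), neutrophils (0.359), astrocytes (0.772) and endothelium (0.926). Single members past the threshold and higher as labelled were Slc1a3 (2.36 ± 0.20) of the astrocyte list, Mag (1.18 ± 0.32) of oligodendrocytes, Pecam1 (1.35 ± 0.36) of endothelium, Cd79b (1.85 ± 0.20) of lymphocytes and Btg2 (1.18 ± 0.29) of dissociation stress, of which Ier3 (-1.75 ± 0.22) was lower. Neuron and lymphocyte lists had 1 and 2 tested members and were not tested.

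In the 3-month set 3269 of 10845 genes differed, 1344 higher and 1925 lower in the libraries labelled PU.1 cKO. Of the calls 41.1% were higher as deposited, 51% after median centring and 53% after quantile normalization, which moved the median difference of all genes from -0.029 to 0.093. Without labelled control replicate 2 there were 2010 higher and 2721 lower genes, and without labelled control replicate 1 there were 805 and 1279. Without labelled cKO replicates 1, 2 and 3 the higher genes numbered 763, 580 and 652 and the lower genes 1314, 960 and 1097. The set lies within 1 run.

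The 3-month difference, as labelled, was compared with that between CK-p25 PU.1 cKO and CK-p25 over 10293 genes tested in both tables, which share no library. Across genes Pearson's r was -0.123 and Spearman's rho -0.139, and 47% of genes had the same sign. The r was -0.060 without CK-p25 replicate 1, -0.067 without CK-p25 PU.1 cKO replicate 1, -0.063 without labelled control replicate 2 and -0.073 without labelled cKO replicate 1, and -0.184 without CK-p25 PU.1 cKO replicate 3. No gene was called in both, since none was called in the second comparison. The r was -0.200 without small RNAs and gene models. Exchanging the 3-month labels would give r and rho the opposite sign and turn shared signs of genes into opposite ones.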

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

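The tests on Spi1 and of spread and partial PU.1 loss were chosen only after their results were seen. The tests of other brain cell RNA and of strain DNA were named before they were run.

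The named genes of the 2 comparisons of PU.1 cKO with its control were searched for opposite directions with non-overlapping groups. Rbm45 and Mlph met this rule. It was not counted over all genes, of which 47% had the same sign in both comparisons, so opposite signs alone are common. The log2 difference of Rbm45 was 2.44 in CK-p25 PU.1 cKO against CK-p25 and -3.44 in the 3-month set as labelled. That of Mlph was -1.17 (9.22 ± 2.19 against 22.0 ± 5.74 FPKM) and 2.37 (25.1 against 4.50 FPKM). Neither gene passed at 4.5 months, both passed at 3 months, and the difference was not tested between the ages. With the 3-month labels exchanged, each gene would go in the same direction at both ages.

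Spi1 lay on the side of the other label in 6 of the 6 libraries of the 3-month set, and the labels contradict themselves there. That count restates the difference that prompted it, so it does not decide whether the labels were exchanged between the 2 groups, which may be so. A rise of the transcript after the deletion itself is the rival reading. The Spi1 difference of -0.49 in CK-p25 PU.1 cKO has the other sign, but age, time after tamoxifen and p25 differ, so it does not decide. List levels in CK, which has intact PU.1, do not settle it either, since age, time after tamoxifen and run differ. Homeostatic genes averaged 10.48 to 10.64 on the log2 scale in CK. They averaged 10.52 to 10.74 in labelled PU.1 cKO and 8.97 to 9.37 in labelled control. In that order cell cycle genes averaged 1.87 to 2.19, 1.55 to 1.77 and 5.27 to 5.96. PU.1 targets averaged 7.33 to 7.44, 7.58 to 7.85 and 7.03 to 7.54. The columns with lower Spi1 are those named for PU.1, and the source names give that name to the samples titled PU.1 cKO. Rbm45, described next, was high in these same libraries and in CK-p25 PU.1 cKO. Both points go with exchanged labels. A rise of the transcript after the deletion was not tested directly, so neither reading is settled. Reads over the deleted part of Spi1, which a gene-level table does not hold, were not examined.

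Rbm45 was at 11.3, 12 and 6.06 FPKM in CK-p25 PU.1 cKO and at 16.6, 13.4 and 18.9 FPKM in the 3-month libraries labelled control, and at 1.41 FPKM or less in the other 9 libraries. The 6 high libraries are those of the lower Spi1 group at each age. DNA of another strain around the altered allele could raise a neighbour, and Rbm45 lies on the chromosome of Spi1 with 38 tested genes between. Among the 400 nearest tested genes 26 (6.5%) had p under 0.05 against 615 (6.21%) of 9905 others (Fisher's exact p = 0.752). A single altered gene would not show in that count, so strain DNA stays open.

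No gene passed between CK-p25 PU.1 cKO and CK-p25, while the same fit called 3384 genes between CK-p25 PU.1 cKO and CK. The spread thus did not prevent calls of changes as large as those, but it may hide smaller ones. In simulation 23.3% of changes of 0.5 and 66.1% of changes of 1 on the log2 scale were recovered in the first comparison. The simulated sets also held changes of 2 and 3, which ease the adjusted threshold. Small changes alone may thus be recovered less often. The level of 30 marker genes of other brain cells was then used as a covariate. The count between CK-p25 PU.1 cKO and CK-p25 stayed at 0 (705 genes at unadjusted p under 0.05, smallest adjusted p = 0.292). That does not exclude that RNA of other brain cells hid a difference, since a covariate costs power with 9 libraries. The lists were not tested with it. PU.1 may be only partly lost, as the Spi1 ratio of 0.713 leaves open, though gene-level FPKM counts parts of the transcript that the deletion leaves. Changes too small for 3 libraries per group also remain possible.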

How the results depend on the processing

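Leaving out genes listed at 0 beside high values, and singling out the fit without CK-p25 replicate 2, were chosen only after the data were seen. Leaving out single libraries was also not planned for the r between the 3-month difference and that of CK-p25 PU.1 cKO from CK-p25. Of the counts and relations 201 were the same under the alternatives and 54 moved. For genes and lists, stronger or weaker means only that the adjusted p crossed 0.05, and reversed that the direction changed. The size of the difference was not used. Of the named genes 894 values were the same, 11 stronger, 13 weaker and 3 reversed, and of the single lists 429 were the same, 15 weaker and 1 reversed. For example, 3-month Spi1 counts as stronger without labelled control replicate 2, at 0.50 against 0.92 in the main fit. The cause of these shifts was not tested.

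With an estimated correlation 0 lists passed in the 3-month set, 0 in CK-p25 against CK and 0 in CK-p25 PU.1 cKO against CK, so no list call holds there. The fry test gave 9 lists at 3 months and 12 in CK-p25 against CK. It gave 0 in CK-p25 PU.1 cKO against CK-p25 and 13 in CK-p25 PU.1 cKO against CK. Quantile normalization gave 2086 higher genes at 3 months. Between CK-p25 PU.1 cKO and CK-p25, no filter gave 1 higher gene, 1 lower gene and 1 list, quantile normalization 1 higher gene, leaving out small RNAs and gene models 1 higher gene, and only the compared libraries 2 higher genes and 3 lists. Only the compared libraries gave 2396 lower genes in CK-p25 PU.1 cKO against CK. Leaving out small RNAs and gene models gave r = -0.200 between the 3-month difference and that of CK-p25 PU.1 cKO from CK-p25. Spi1 in CK-p25 against CK turned to -0.39 after quantile normalization, -0.02 without CK replicate 2 and -0.10 without CK-p25 replicate 3. The cell cycle median in CK-p25 PU.1 cKO against CK turned to 0.012 with a filter at 5 FPKM. Without genes listed at 0 beside 100 FPKM or more, 3278 genes differed at 3 months, 3413 between CK-p25 and CK, 0 between CK-p25 PU.1 cKO and CK-p25 and 3386 between CK-p25 PU.1 cKO and CK. Without CK-p25 replicate 2, 3185 genes differed between CK-p25 and CK, and Spi1 differed by 0.156.

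Leaving out each library in turn gave 580 to 2010 higher genes, 960 to 2721 lower genes and 9 to 12 lists at 3 months. CK-p25 against CK ranged over 1373 to 2360, 902 to 2162 and 10 to 11. CK-p25 PU.1 cKO against CK-p25 ranged over 0 to 12, 0 to 13 and 0 to 8, and CK-p25 PU.1 cKO against CK over 1453 to 2650, 908 to 2398 and 6 to 9. Genes called in opposite directions numbered 0 to 6, the median step toward CK ran from 0.026 to 0.107, and r from -0.184 to -0.060. Within the run of 8 libraries, CK-p25 PU.1 cKO against CK-p25 had 0 higher and 0 lower genes and 2 lists past the threshold. Correlations of same-numbered libraries ran from -0.049 to 0.17, so the numbers do not pair. A block on them gave 3381, 3307, 0 and 3251 genes in the 3-month set, CK-p25 against CK, CK-p25 PU.1 cKO against CK-p25, and CK-p25 PU.1 cKO against CK. With the block Spi1 passed in the last (adjusted p = 0.0237).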

Other observations

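The comparison of the 3-month set with CK-p25, its gene lists, and the genes of the split with the highest other count were looked at only after the values were seen. The splits themselves were named before they were run. Spp1 was lower at 3 months as labelled (-5.99 ± 0.47) and higher in CK-p25 than in CK (7.68 ± 0.37). Ch25h (-5.45 ± 0.44 and 5.25 ± 0.31) and Gpnmb (-3.45 ± 0.34 and 6.09 ± 0.47) did the same. Gpr165 (4.13 ± 0.29 and -5.02 ± 0.31), Il7r (3.25 ± 0.24 and -2.79 ± 0.29) and Mycl (3.27 ± 0.28 and -2.52 ± 0.22) went the other way. Of the disease-associated list 11 of 22 members were lower at 3 months as labelled and higher in CK-p25, as were 8 of 14 glycolysis and 7 of 20 interferon genes, while 11 of 18 homeostatic genes were higher and then lower. Of 21 cell cycle genes 4 were lower in both and 3 lower then higher, and of 12 complement genes 2 were higher in both and 1 lower then higher. Exchanged labels would turn opposite directions into shared ones and the reverse.

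Some genes moved in the same direction in both comparisons, with the 3-month set as labelled. Lag3 (4.02 ± 0.17 and 2.49 ± 0.31), Il4i1, an amino acid oxidase gene (1.85 ± 0.22 and 2.86 ± 0.27), and the inhibitory receptor gene Cd22 (1.55 ± 0.31 and 3.58 ± 0.43) were higher in both. The Notch target gene Hes1 (-1.72 ± 0.19 and -1.67 ± 0.26) and the lamin B receptor gene Lbr (-1.04 ± 0.21 and -1.43 ± 0.10) were lower in both. Over 10293 genes r was -0.393 and rho -0.482 with 31.9% of signs shared, and 753 genes were lower then higher (306 in independent lists), 523 higher then lower (191), 98 higher in both (237) and 47 lower in both (246). The r was -0.397 after quantile normalization, -0.406 over 10023 genes outside the lists and -0.340 to -0.406 on leaving out each of 12 libraries. Against CK-p25 PU.1 cKO minus CK, r was -0.434.

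The 6 libraries of a comparison divide into 10 splits of 3 against 3, so the share of splits with as many genes as the real one is never under 0.1. In the 3-month set 1 of 10 splits, the real one, reached 3269 genes and the highest other had 4. In CK-p25 against CK it was 1 of 10 (3412, highest other 4), and in CK-p25 PU.1 cKO against CK 1 of 10 (3384, highest other 2). The splits are too few to decide on chance in these 3 comparisons. For CK-p25 PU.1 cKO against CK-p25 the real count of 0 is reached by all 10 splits by construction, so the splits test nothing there, and the highest other had 97.

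That split with 97 genes set CK-p25 PU.1 cKO replicate 1 and CK-p25 replicates 1 and 3 apart from the other 3 libraries, in which 95 genes were higher, among them Mbp (2.52), Gfap (2.24) and Camk2a (2.61), markers of oligodendrocytes, astrocytes and neurons. The mean marker level of other brain cells was 1.71, 2.65 and 2.92 in CK-p25 PU.1 cKO, 1.89, 3.12 and 1.43 in CK-p25 and 1.45, 2.04 and 1.80 in CK. As a covariate that level was associated with 225 higher and 21 lower genes, and left 2175 and 1689 genes between CK-p25 and CK. The marker genes that form the level were not removed from the tested genes, so some of these associations may follow by construction.

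Xist, expressed in female cells, was at 0.0321 FPKM or less in the 15 RNA libraries, and Ddx3y, a Y-linked gene, at 6.36 to 14.9 FPKM. The labels state female mice for the chromatin samples and no sex for the RNA.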
